A study of Mus musculus with 8 samples.

How the data were processed

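RNA was measured by sequencing in 8 mouse libraries, and the deposited files hold whole-number read counts per gene that the authors made before deposit. Per the submitters' processing notes, Trimmomatic, DESeq2 and the mouse build mm10 were used. Their versions, the aligner, the counting program and the strand setting are not given in the sources used here. Per the labels, total RNA was extracted with Trizol from FACS-sorted germinal center B cells and from B cells enriched with beads from the spleen and then activated. How the cells were activated, whether replicates came from separate mice, and which exons the knockout removes are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, with 2 libraries per group.

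Each file lists 55401 gene identifiers, of which 55141 are in GENCODE M21 (GRCm38, the assembly of mm10), whose symbols, coordinates and biotypes were used. The 5 summary entries that name no gene stayed out of library sizes and tests. Reads that the counting assigned to no feature were 47.2% to 53.9% and ambiguous reads 1.12% to 1.26% of all entries. The first share may include reads on the strand opposite to a gene, since the strand setting is not given. Total counts on genes ran from 8777425 to 11414559 per library, so a gene at 1 CPM rests on 8.78 to 11.4 counts in a library, and at such levels counting error sets most of the spread. Intervals and floors given for genes with 3 or fewer counts in a group cover counting error only.

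Strand was checked on the counts. Genes that lie wholly within exons of a gene on the opposite strand (51 to 60 per library) had median count densities of 1.08 to 1.59 times those of the host gene, so reads of a gene and its antisense partner may be mixed. Whether the library or the counting lost the strand was not tested. Among named genes, more than 10% of the exon length overlaps opposite exons for Igf2bp3 (18.7%), H1f10 (17.5%), Cd274 (14.1%), Ctsb (12.8%), Hmgcs1 (12.1%) and Cd9 (10.7%), and these values are uncertain. Genes with near-identical copies, such as hemoglobin, PYHIN, Ly6 and immunoglobulin constant genes, are uncertain in the same way.

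Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. KO was compared with WT within each cell type, from the 4 libraries of that cell type. WT germinal center B cells were compared with WT activated B cells, and the difference of the 2 KO effects was tested in 1 fit of the 4 group means over all 8 libraries. CPM values beside a comparison use the scaling of that comparison, so the same group differs slightly between comparisons. Median log2 fold changes over all tested genes were -0.00443, 0.000623 and -0.0338 in the 3 comparisons.

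Before the data were examined, 40 gene lists were fixed for B cell states, signaling, metabolism, cell cycle, chromatin and markers of other cell types. Of 1093 distinct symbols, 1081 matched the annotation, 46 of them by an older symbol. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry (limma 3.58.1), with Benjamini-Hochberg adjustment over the lists. This left 36, 38 and 39 lists in germinal center B cells, activated B cells and the WT comparison. Platelet and megakaryocyte markers had too few tested members in all 3 and are given only as summed levels. Counts adjusted over the list alone apply the adjustment to the members of 1 list.

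The genes named in the text were chosen by a rule fixed before the data were examined. For each KO comparison it takes Jmjd1c and the 10 highest and 10 lowest log2 fold changes among genes that passed, had a mean count of at least 50 and had every KO library on the same side of every WT library. Predicted genes, clones, genes marked as pseudogenes in their symbol and immunoglobulin or T cell receptor variable segments were left out. It takes 6 genes per direction for the WT comparison, 5 per direction for the difference of KO effects, and up to 4 members per list with the lowest p, of which the text names a part. Some genes that the rule takes are not reported here. In activated B cells Jmjd1c was itself among the 10 lowest, so 9 other genes lower in KO were named there.

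The procedure was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. At a 2-fold change edgeR recovered 89.6% of changed genes for the germinal center comparison (13125 genes), 82.1% for activated B cells (13922 genes), 85.1% for the WT comparison (13944 genes) and 67.2% for the difference of KO effects (14756 genes). At 1.5-fold these shares were 65.7%, 74.6%, 68.7% and 47.8%, and false calls were 5.06%, 6.59%, 3.45% and 7.8% of all calls. A simulated changed list was called in each of the first 3 comparisons, and 0 of 36, 38 and 38 unchanged lists were. Genes were drawn independently of each other, so the simulation does not show how often lists of correlated genes are called falsely. The simulation also used spreads fitted by edgeR itself and changed only 200 genes. In the real data 6698 of 13350 genes passed in the germinal center comparison and 11852 of 14426 in the WT comparison. The simulated shares may therefore not carry over to changes that broad.

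Alternatives fixed beforehand were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, limma-voom, a spread shared over all 8 libraries, immunoglobulin genes left out, an adjusted p under 0.10, a test against a minimum fold of 1.5, a replicate block and leaving out each library in turn. When 1 library of a group is left out, the remaining one is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The tests of explanations in the closing part were all set up after the results they bear on had been seen.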

Results

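Gene-level read counts were analysed from 8 mouse RNA-seq libraries that fall into 4 groups of 2. Germinal center B cells, which divide and mutate their antibody genes inside B cell follicles, were sorted by FACS from the spleen. Activated B cells were splenic B cells enriched with a biotinylated pan-B reagent and streptavidin beads and then stimulated. Each cell type came from wild-type (WT) C57BL/6 mice and from mice with a B cell knockout (KO) of Jmjd1c, which encodes a Jumonji-domain protein of the histone H3K9 demethylase family. The libraries held between 8777425 and 11414559 counts on genes, and levels are given as TMM-scaled CPM, the standard unit of counts relative to library size. Values with ± are means and SDs over the n = 2 libraries of a group, and log2 fold changes are given with their SE.

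Replicate libraries lay close together. Biological coefficients of variation were 1.89% and 2.48% for KO and WT germinal center B cells, and 4.11% and 3.87% for KO and WT activated B cells. Counts of replicates still differed by more than sampling noise, with chi-square per degree of freedom from 1.39 to 2.40, so no pair was a library deposited again. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The first principal component held 87.7% of the variance and separated the cell types, and the second held 6.25% and separated KO from WT germinal center B cells. On the first component, KO germinal center B cells also lay nearer the activated B cells, at -77.05 and -76.3 against -112.3 and -112.6 in WT.

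Jmjd1c transcripts were lower in both KO preparations, by much less in germinal center than in activated B cells. In activated B cells the gene (ENSMUSG00000037876.17, chromosome 10, 67096125 to 67256326, plus strand, GRCm38) fell by 47.9%, from 293 ± 6.70 to 153 ± 12.6 CPM (log2 fold change -0.94, SE 0.06, adjusted p = 1.81e-11). In germinal center B cells it fell by 13.2%, from 176 ± 11.8 to 153 ± 3.63 CPM (log2 fold change -0.20, SE 0.04, adjusted p = 1.66e-05). Raw counts per library were 1341 and 1330 in KO and 1850 and 1950 in WT germinal center B cells. They were 1329 and 1520 in KO and 2656 and 2852 in WT activated B cells. The KO effects differed between the cell types by 0.74 on the log2 scale (SE 0.07, adjusted p = 1.39e-14, all 8 libraries in 1 fit). The labels do not give the deleted exons, and counts summed over the whole gene include reads from any exon that remains, so these values check the labels only in direction.

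**Figure D1:**
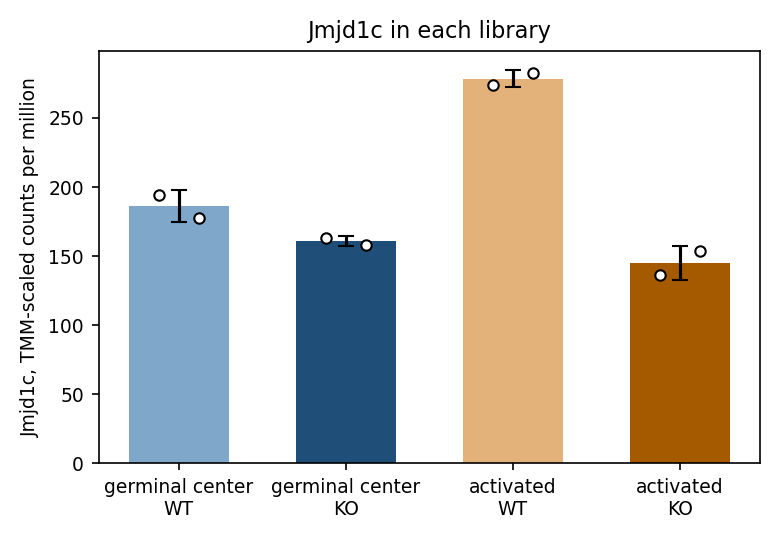
Jmjd1c in each library, in TMM-scaled CPM over all 8 libraries (bars, group means; whiskers, SD; circles, the 2 libraries of a group). Means were 186 ± 11.5 and 161 ± 3.54 in WT and KO germinal center B cells and 278 ± 6.01 and 145 ± 12.3 in WT and KO activated B cells.

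The first comparison asked which transcripts differ between KO and WT germinal center B cells. KO cells held more transcripts of interferon-induced genes, of memory B cell genes and of the mitochondrial genome. They held fewer transcripts of the germinal center program, of the cell cycle and of nuclear-encoded respiratory chain genes. Single genes were ranked by fold only among called genes with a mean count of at least 50 and every KO library on the same side of every WT library, leaving out predicted genes and antibody variable segments, so genes of lower counts can exceed them. Within these limits the interferon-induced GTPase gene Mx1 (chromosome 16, 97447035 to 97462907) was highest, at 24.2 ± 1.24 against 0.980 ± 0.167 CPM (log2 fold change 4.62, SE 0.23, adjusted p = 2.09e-91). The planar polarity cadherin gene Celsr1 (chromosome 15, 85898929 to 86033777) was lowest, at 4.58 ± 0.242 against 25.1 ± 0.835 CPM (log2 fold change -2.45, SE 0.16, adjusted p = 8.07e-50). Of 13350 genes tested, 6698 passed, 3346 higher and 3352 lower in KO cells, of which 972 and 227 differed by more than 2-fold.

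Other genes with the highest rises within these limits were Hba-a1 (4.47, SE 0.26), an alpha chain of hemoglobin, and the interferon-induced Oas2 (4.18, SE 0.20), which encodes an oligoadenylate synthetase. Next came Sdc3 (4.09, SE 0.27), a syndecan, Plac8 (4.06, SE 0.09), and Ptpn14 (4.0, SE 0.30), a tyrosine phosphatase. Tmem154 (3.83, SE 0.17), the galectin-3-binding protein gene Lgals3bp (3.69, SE 0.22), the interferon-induced Rtp4 (3.64, SE 0.29) and the beta hemoglobin gene Hbb-bs (3.61, SE 0.20) followed. Plac8 was the most abundant of these, at 136 ± 2.59 against 8.12 ± 0.466 CPM, and the hemoglobin genes stayed at 17.7 ± 2.52 CPM (Hba-a1) and 23.8 ± 3.62 CPM (Hbb-bs) in KO cells. Among the lowest genes within the limits were Nt5e (-2.23, SE 0.11), which encodes the ectonucleotidase CD73, Fgf11 (-2.14, SE 0.18), of the fibroblast growth factor family, and Pcyt1b (-2.13, SE 0.18), of phosphatidylcholine synthesis. Igf2bp3 (-2.04, SE 0.15), an RNA-binding protein gene, is uncertain because 18.7% of its exon length overlaps exons on the opposite strand. Osbpl3 (-1.99, SE 0.12), an oxysterol-binding protein gene, Serpinf1 (-1.92, SE 0.27), of the serpin family, Fads2 (-1.91, SE 0.14), a fatty acid desaturase gene, Abi2 (-1.84, SE 0.19), an Abl interactor gene, and Palm (-1.82, SE 0.11), which encodes paralemmin, completed the set. The highest adjusted p among these 20 genes was 3.5e-12 (Serpinf1). Reads of Hba-a1 and Hbb-bs may be split with their near-identical copies, so their levels are uncertain.

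Genes of the germinal center program fell in KO germinal center B cells. Of 32 germinal center B cell genes tested, 27 fell, 3 rose and 2 did not pass, with 27 and 3 adjusted over the list alone. The median log2 fold change was -0.49 (camera adjusted p = 5.92e-26, and adjusted p = 0.0701 with an estimated correlation). Gcsam, which encodes a germinal center signaling adaptor, fell from 332 ± 4.90 to 97.7 ± 3.12 CPM (log2 fold change -1.76, SE 0.04). Mybl1, of the MYB transcription factor family, fell from 734 ± 22.3 to 251 ± 2.94 CPM (log2 fold change -1.55, SE 0.04). In the dark zone, where these cells divide, 21 of 23 genes fell, 0 rose and 2 did not pass (21 and 0 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 2.23e-11, and adjusted p = 0.0701 with an estimated correlation). Examples beside Gcsam were Cdc20 (-0.66), an activator of the anaphase-promoting complex, and Polh (-0.73), a translesion DNA polymerase gene. Light zone genes, expressed where the cells meet antigen and T cells, moved the other way, with 22 of 28 higher, 1 lower and 5 not passing (22 and 1 adjusted over the list alone). Their median was 0.46 (camera adjusted p = 6.63e-09, and adjusted p = 0.0701 with an estimated correlation), with Ccr6 (2.87), a chemokine receptor gene, and the early activation marker Cd69 (1.5) as examples.

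Cell cycle genes fell together. Of 44 S phase genes, 37 fell, 1 rose and 6 did not pass (38 and 2 adjusted over the list alone). The median was -0.42 (camera adjusted p = 7.74e-15, and adjusted p = 0.0701 with an estimated correlation). Mcm6, which encodes a subunit of the replicative helicase, fell from 515 ± 3.03 to 332 ± 15.2 CPM (-0.63). Of 43 G2 and M phase genes, 40 fell, 0 rose and 3 did not pass (41 and 0 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 2.5e-15, and adjusted p = 0.0701 with an estimated correlation). Top2a (-0.47), a DNA topoisomerase gene, and Hmgb2 (-0.69), a chromatin protein gene, were examples. Replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, gave 2 higher, 1 lower and 27 not passing of 30 (2 and 0 adjusted over the list alone), with camera adjusted p = 0.93.

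Memory B cell genes were higher in KO germinal center B cells. Of 26 memory B cell genes, 20 rose, 3 fell and 3 did not pass (21 and 3 adjusted over the list alone). The median was 1.73 (camera adjusted p = 5.68e-29, and adjusted p = 0.0701 with an estimated correlation). Klf2, a transcription factor gene of recirculating lymphocytes, rose from 40.4 ± 0.721 to 190 ± 3.8 CPM (log2 fold change 2.23, SE 0.06). Such genes are not confined to memory B cells, so the list does not tell memory from other recirculating B cells. Mature B cell identity genes were split, with 17 of 30 higher, 8 lower and 5 not passing (17 and 8 adjusted over the list alone) and a median of 0.17 (camera adjusted p = 3.14e-11, and adjusted p = 0.0701 with an estimated correlation). The constant genes of the first 2 antibody classes a B cell makes were among those that rose, with Ighd at 555 ± 4.39 against 134 ± 1.39 CPM (2.05, SE 0.04) and Ighm at 5490 ± 80.2 against 1550 ± 6.89 CPM (1.83, SE 0.03). Immunoglobulin constant genes as a list gave 7 of 12 higher and 5 lower (7 and 5 adjusted over the list alone), with 0 not passing, a median of 0.35 (camera adjusted p = 4.57e-06, and adjusted p = 0.135 with an estimated correlation) and Ighg2b, of IgG2b, among those that fell (-0.62).

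All 45 interferon response genes tested rose in KO germinal center B cells (45 and 0 adjusted over the list alone). The median log2 fold change was 2.21, with quartiles of 1.25 and 2.90 (camera adjusted p = 2.63e-42, and adjusted p = 0.0701 with an estimated correlation). Ifi203, of the interferon-inducible PYHIN family, rose by 2.65 (SE 0.05), and Ddx58, which encodes the RNA sensor RIG-I, rose by 2.65 (SE 0.09). PYHIN genes are similar in sequence, so the count of 1 of them is uncertain. Of 25 genes of MHC class II and antigen presentation, 16 rose, 4 fell and 5 did not pass (16 and 4 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 2.23e-11, and adjusted p = 0.0701 with an estimated correlation). The 2 examples, H2-K1 (1.30) and B2m (1.08), encode chains of MHC class I.

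Plasma cell genes were split, with 17 of 31 higher, 8 lower and 6 not passing (18 and 8 adjusted over the list alone) and a median of 0.49 (camera adjusted p = 0.0156, and adjusted p = 0.243 with an estimated correlation). The transcription factor gene Irf4 rose by 1.36, while Zbtb20, another transcription factor gene, changed by -0.92. Of 41 genes of protein folding and secretion in the endoplasmic reticulum, 24 rose, 3 fell and 14 did not pass (24 and 3 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.000134, and adjusted p = 0.164 with an estimated correlation), with the disulfide isomerase gene Pdia4 (1.84) and the chaperone gene Hspa5 (0.57) as examples. B cell receptor signaling genes gave 18 of 36 higher, 6 lower and 12 not passing (18 and 6 adjusted over the list alone), with camera adjusted p = 0.000332, and adjusted p = 0.135 with an estimated correlation. NF-kappaB target genes gave 20 of 31 higher, 2 lower and 9 not passing (20 and 2 adjusted over the list alone), with camera adjusted p = 0.000332, and adjusted p = 0.24 with an estimated correlation. The NF-kappaB subunit gene Nfkb1 rose by 0.62. JAK-STAT3 and cytokine response genes gave 20 of 36 higher, 10 lower and 6 not passing (20 and 10 adjusted over the list alone), with camera adjusted p = 0.00194, and adjusted p = 0.135 with an estimated correlation. The interleukin 10 receptor gene Il10ra rose by 1.72.

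Genes of the respiratory chain moved apart by the genome that encodes them. All 13 mitochondrially encoded genes tested rose (13 and 0 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 1.53e-21, and adjusted p = 0.0701 with an estimated correlation). The cytochrome oxidase gene mt-Co1 went from 24300 ± 923 to 44800 ± 1670 CPM and the cytochrome b gene mt-Cytb rose by 0.87. Mitochondrial genes took 9.20% and 9.52% of the counts in the KO libraries against 5.51% and 5.27% in WT, a share that also moves with RNA quality. Of 67 nuclear-encoded oxidative phosphorylation genes, 52 fell, 0 rose and 15 did not pass (54 and 0 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 1.67e-07, and adjusted p = 0.24 with an estimated correlation). Atp5b (-0.37), of ATP synthase, and Cox6a1 (-0.50), of cytochrome oxidase, were examples.

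Markers of other cell types were also higher in the sorted KO germinal center B cells, beside the interferon and memory B cell genes. Of 18 monocyte and macrophage markers, 15 rose, 0 fell and 3 did not pass (15 and 0 adjusted over the list alone), with a median of 2.21 (camera adjusted p = 4.57e-06, and adjusted p = 0.139 with an estimated correlation). Mpeg1, a pore-forming protein gene of phagocytes, rose to 73.3 ± 6.14 from 15.6 ± 0.281 CPM, and the lysosomal protease gene Ctsb rose by 0.71. Of 8 erythroid markers, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 2.79 (camera adjusted p = 0.000224, and adjusted p = 0.211 with an estimated correlation). Dendritic cell markers gave 6 of 11 higher, 0 lower and 5 not passing (7 and 0 adjusted over the list alone), with camera adjusted p = 0.0282, and adjusted p = 0.24 with an estimated correlation. Stromal and follicular dendritic cell markers gave 5 of 6 higher, 0 lower and 1 not passing (5 and 0 adjusted over the list alone), with camera adjusted p = 0.00235, and adjusted p = 0.157 with an estimated correlation. T cell markers gave 8 of 14 higher, 1 lower and 5 not passing (10 and 2 adjusted over the list alone), with camera adjusted p = 0.079. Summed over each list, KO and WT cells held 898 ± 16.2 and 727 ± 17.6 CPM of monocyte, 178 ± 9.0 and 139 ± 7.06 CPM of erythroid, and 299 ± 0.295 and 220 ± 1.07 CPM of T cell markers. These sums rose by less than the list medians, so abundant members that changed little carry most of them. In WT cells Hba-a1 and Hbb-bs stood at only 0.787 and 1.93 CPM. Such sums therefore do not measure RNA of other cell types in the sorted cells. The sums for platelet and megakaryocyte markers were 83.1 ± 0.0693 and 103 ± 0.789 CPM, and those for neutrophil markers 3.04 ± 0.900 and 1.04 ± 0.583 CPM.

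Lists of several other processes did not pass in KO germinal center B cells by camera. These were glycolysis genes (8 of 26 higher, 12 lower, adjusted p = 0.05 after rounding), cytosolic ribosomal protein genes (6 of 78 higher, 25 lower, adjusted p = 0.164) and Myc and ribosome biogenesis genes (13 of 45 higher, 12 lower, adjusted p = 0.784). Apoptosis regulators (7 of 27 higher, 11 lower, adjusted p = 0.87), p53 target genes (8 of 24 higher, 7 lower, adjusted p = 0.905) and genes used as B cell Cre drivers (3 of 6 higher, 2 lower, adjusted p = 0.87) did not pass either. In all, 27 of 36 lists tested passed with the preset correlation, 20 higher and 7 lower, and 0 passed with a correlation estimated from 2 residual degrees of freedom (14 at an unadjusted p under 0.05). Median and mean differed in sign for glycolysis genes (-0.17 and 0.01), apoptosis regulators (-0.09 and 0.08) and histone genes (0.01 and -0.02), and the Cre driver genes had a median of 0.28 while camera put them lower. By fry, which tests whether a list moves 1 way on balance and does not compare it with other genes, 31 passed. The 41 genes named from the lists in this comparison all passed on their own, with adjusted p at most 5.57e-13 and SE from 0.02 to 0.12. A test against a minimum fold of 1.5 kept 1247 of the 6698 genes, 77.5% of them higher.

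**Figure D2:**
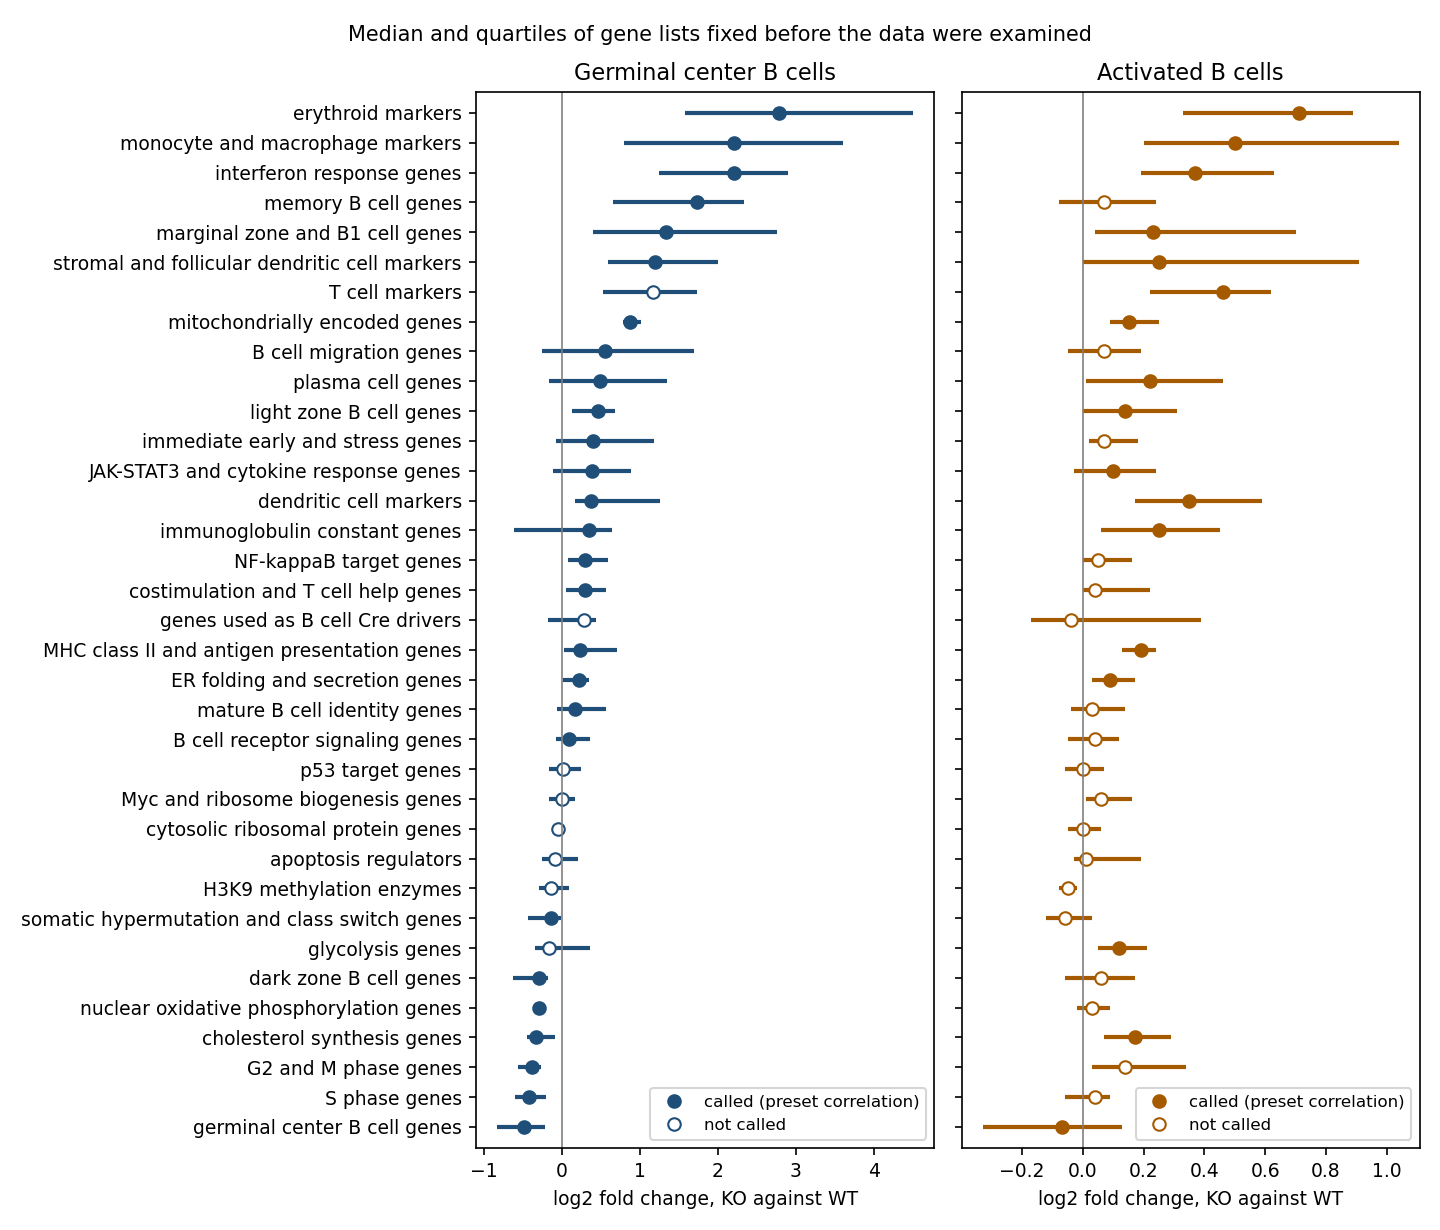
Median (points) and quartiles (lines) of the log2 fold change, KO against WT, for the lists tested in both cell types, with filled points for lists called by camera with the preset correlation. The horizontal scales differ between the panels: in germinal center B cells the medians span from -0.49 (germinal center B cell genes) to 2.79 (erythroid markers), and in activated B cells the median of erythroid markers is 0.71.

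The second comparison made the same contrast in activated B cells. KO preparations held more transcripts of neutrophils, monocytes and red blood cells, more interferon response transcripts and more transcripts of several immunoglobulin constant genes. They held fewer transcripts of Gcsam and Mybl1, which belong to the germinal center program. Within the same limits on count and separation, the peptide transporter gene Slc15a2 (ENSMUSG00000022899.9, chromosome 16, 36750177 to 36784962) stood far above the rest, at 110 ± 2.30 CPM in KO against 0.641 ± 0.168 CPM in WT (log2 fold change 7.40, SE 0.15, adjusted p = 2.59e-21). Ifi208 (chromosome 1, 173673675 to 173698395), of the interferon-inducible PYHIN family, was lowest within these limits, at 4.56 ± 0.586 against 39.4 ± 5.47 CPM (log2 fold change -3.11, SE 0.15, adjusted p = 8.84e-14). Of 14110 genes tested, 885 passed, 684 higher and 201 lower in KO, of which 214 and 31 differed by more than 2-fold.

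Neutrophil markers had the highest median of the 38 lists tested in KO activated B cells. Of 17 neutrophil markers, 16 rose, 0 fell and 1 did not pass (17 and 0 adjusted over the list alone). The median log2 fold change was 1.78 (camera adjusted p = 1.7e-140, and adjusted p = 0.183 with an estimated correlation). Their summed level was 2380 ± 320 CPM in KO and 646 ± 53.4 CPM in WT activated B cells. The granule protein genes Ngp (809 ± 135 against 208 ± 18.1 CPM) and Ltf (407 ± 48.3 against 119 ± 3.04 CPM) and the calprotectin subunit gene S100a9 (473 ± 54.0 against 123 ± 13.5 CPM) were the most abundant. Within the limits for ranking, most of the genes with the highest fold changes after Slc15a2 are genes of granulocytes or monocytes. They were Fcnb (2.26, SE 0.19), a ficolin gene, Elane (2.24, SE 0.18), neutrophil elastase, S100a8 (2.09, SE 0.10), the other calprotectin subunit, Camp (2.09, SE 0.10), cathelicidin, Chil3 (2.08, SE 0.08), a chitinase-like protein gene, and Ctsg (2.06, SE 0.24), cathepsin G. The remaining ones were Ighg2b (2.12, SE 0.06), the IgG2b constant gene, at 729 ± 59.0 against 167 ± 10.6 CPM, Ifitm6 (2.03, SE 0.17), of the interferon-induced transmembrane family, and Ly6a2 (1.97, SE 0.14), annotated as a transcribed pseudogene, whose reads may be shared with related genes.

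Markers of monocytes and red blood cells were higher too. Most members of the T cell, dendritic cell, NK cell and stromal lists did not pass. Their medians were raised as well, at 0.46, 0.35, 0.51 and 0.25, and those of T and NK cell markers lay close to the monocyte median. Of 25 monocyte and macrophage markers, 13 rose, 0 fell and 12 did not pass (15 and 0 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 2.64e-24, and adjusted p = 0.247 with an estimated correlation). Lyz2, the lysozyme gene of myeloid cells, stood at 872 ± 63.7 against 458 ± 31.6 CPM, and the monocyte chemokine receptor gene Ccr2 rose by 1.54. Of 15 erythroid markers, 9 rose, 0 fell and 6 did not pass (9 and 0 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 1e-13, and adjusted p = 0.183 with an estimated correlation). Hba-a1 rose to 350 ± 42.6 from 213 ± 9.63 CPM, and the anion exchanger gene Slc4a1 rose by 0.93. T cell markers gave 1 of 23 higher, 0 lower and 22 not passing (7 and 0 adjusted over the list alone), with camera adjusted p = 0.0101, and adjusted p = 0.247 with an estimated correlation. Dendritic cell markers gave 1 of 14 higher, 0 lower and 13 not passing (1 and 0 adjusted over the list alone), with camera adjusted p = 0.0171, and adjusted p = 0.292 with an estimated correlation. NK cell markers gave 2 of 7 higher, 0 lower and 5 not passing (3 and 0 adjusted over the list alone), with camera adjusted p = 0.000697, and adjusted p = 0.372 with an estimated correlation. Tyrobp (0.88), 1 of the 2, encodes a signaling adaptor that myeloid cells also make. Stromal and follicular dendritic cell markers gave 2 of 8 higher, 1 lower and 5 not passing (2 and 1 adjusted over the list alone), with camera adjusted p = 0.0208, and adjusted p = 0.276 with an estimated correlation. Summed over each list, KO and WT preparations held 2800 ± 150 and 2040 ± 72.2 CPM of monocyte, 1210 ± 131 and 805 ± 5.02 CPM of erythroid, and 322 ± 4.40 and 288 ± 0.226 CPM of T cell markers. For NK cell markers the sums were 133 ± 21.9 and 78 ± 3.81 CPM, and for dendritic cell markers 1130 ± 5.35 and 1100 ± 28.5 CPM.

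**Figure D3:**
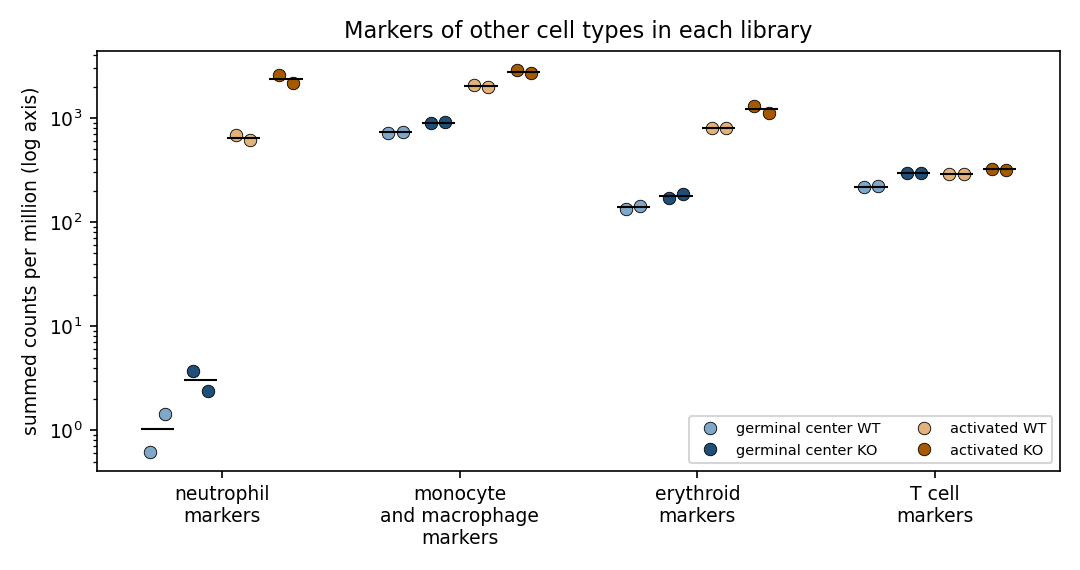
Summed TMM-scaled CPM of marker lists for other cell types, on a log axis, with 1 point per library and lines at the group means. Neutrophil markers sum to 2380 ± 320 in KO and 646 ± 53.4 in WT activated B cells and to 3.04 ± 0.900 and 1.04 ± 0.583 in KO and WT germinal center B cells. In germinal center B cells the monocyte, erythroid and T cell sums rest mostly on abundant members that changed little, so they do not measure RNA of those cells.

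Interferon response genes were higher in KO activated B cells too, with 20 of 47 higher, 0 lower and 27 not passing (34 and 0 adjusted over the list alone). The median was 0.37 (camera adjusted p = 4.71e-18, and adjusted p = 0.183 with an estimated correlation). Oasl2 (1.05) and Ifit3 (1.23), both induced by interferon, were examples. Genes of MHC class II and antigen presentation gave 13 of 25 higher, 0 lower and 12 not passing (19 and 0 adjusted over the list alone), with camera adjusted p = 1.53e-07, and adjusted p = 0.247 with an estimated correlation. Tap1 (0.27), a peptide transporter gene of MHC class I loading, and H2-Aa (0.30), an MHC class II chain gene, rose. Immunoglobulin constant genes gave 6 of 12 higher, 0 lower and 6 not passing (8 and 0 adjusted over the list alone), with camera adjusted p = 2.5e-16, and adjusted p = 0.247 with an estimated correlation. Besides Ighg2b, Ighg1 rose from 54.1 ± 5.10 to 102 ± 6.92 CPM (0.92, SE 0.08) and Ighe rose by 2.0 (SE 0.35), the classes of IgG1 and IgE.

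The germinal center list in activated B cells gave 2 of 32 higher, 6 lower and 24 not passing (5 and 7 adjusted over the list alone), with camera adjusted p = 0.0201, and adjusted p = 0.247 with an estimated correlation. Gcsam fell from 5.48 ± 0.678 to 0.484 ± 0.233 CPM (log2 fold change -3.47, SE 0.40) and Mybl1 from 10.3 ± 0.207 to 2.68 ± 0.336 CPM (-1.93, SE 0.22). In WT germinal center B cells, scaled together with the WT activated libraries, Gcsam and Mybl1 stood at 352 ± 4.13 and 779 ± 21.3 CPM. Besides Ifi208 and Mybl1, genes with the lowest fold changes within the limits for ranking were Col5a3 (-1.5, SE 0.24), a collagen gene, Gad1 (-1.15, SE 0.13), a glutamate decarboxylase gene, and Zfp827 (-1.14, SE 0.19), a zinc finger protein gene. Abi2 (-0.90, SE 0.18), Pfn2 (-0.76, SE 0.20), a profilin gene, Rell1 (-0.75, SE 0.10) and Dnah8 (-0.69, SE 0.11), a dynein heavy chain gene, made up the rest of the set, in which Jmjd1c (-0.94) also falls. Their highest adjusted p was 0.0177 (Pfn2). Pfn2 did not pass without KO replicate 1 (adjusted p = 0.0637), without WT replicate 2 (0.157), with no filter (0.0653) or by DESeq2 (0.5), in a range of 0.00502 to 0.5 over all settings. Abi2 did not pass by DESeq2 (adjusted p = 0.158, in a range of 9.74e-05 to 0.158).

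In several further lists most members did not pass in KO activated B cells, although the list as a whole passed with the preset correlation. Light zone genes gave 5 of 29 higher, 0 lower and 24 not passing (10 and 1 adjusted over the list alone), with camera adjusted p = 0.00167, and adjusted p = 0.247 with an estimated correlation. Plasma cell genes gave 5 of 30 higher, 1 lower and 24 not passing (10 and 2 adjusted over the list alone), with camera adjusted p = 8.16e-05, and adjusted p = 0.247 with an estimated correlation. Jchain (0.62), the joining chain of secreted IgM and IgA, and Prdm1 (0.64), the transcription factor gene of plasma cell differentiation, rose. Genes of endoplasmic reticulum folding and secretion gave 6 of 41 higher, 0 lower and 35 not passing (9 and 0 adjusted over the list alone), with camera adjusted p = 0.00344, and adjusted p = 0.247 with an estimated correlation. JAK-STAT3 and cytokine response genes gave 5 of 38 higher, 0 lower and 33 not passing (5 and 0 adjusted over the list alone), with camera adjusted p = 0.0101, and adjusted p = 0.247 with an estimated correlation. The interleukin 5 receptor gene Il5ra rose by 0.94. Glycolysis genes gave 6 of 28 higher, 0 lower and 22 not passing (11 and 0 adjusted over the list alone), with camera adjusted p = 0.000105, and adjusted p = 0.247 with an estimated correlation. Their example Hk3 (1.21) encodes a hexokinase found mainly in myeloid cells. Mitochondrially encoded genes gave 2 of 10 higher, 0 lower and 8 not passing (3 and 0 adjusted over the list alone), with camera adjusted p = 0.0245, and adjusted p = 0.511 with an estimated correlation. Y-linked and X-inactivation genes gave 0 of 5 higher, 1 lower and 4 not passing (0 and 2 adjusted over the list alone), with camera adjusted p = 0.00834, and adjusted p = 0.247 with an estimated correlation. The Y-linked translation factor gene Eif2s3y fell by 0.34.

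Cell cycle genes did not pass in activated B cells, with 0 of 44 S phase genes and 1 of 43 G2 and M phase genes higher, 0 of either lower, and camera adjusted p = 0.961 and 0.105. The same held for nuclear oxidative phosphorylation (0 of 67 called, adjusted p = 0.636), dark zone (3 of 23 lower, adjusted p = 0.304), memory B cell (5 of 25 higher and 2 lower, adjusted p = 0.304) and mature B cell identity genes (4 of 30 higher and 1 lower, adjusted p = 0.412). B cell receptor signaling (3 of 36 higher and 1 lower, adjusted p = 0.504), NF-kappaB target (1 of 32 higher, adjusted p = 0.222), cytosolic ribosomal protein (1 of 78 lower, adjusted p = 0.686) and Myc and ribosome biogenesis genes (0 of 45 called, adjusted p = 0.15) did not pass. Nor did apoptosis regulators (0 of 27 called, adjusted p = 0.417), p53 target genes (1 of 25 higher and 1 lower, adjusted p = 0.975) or genes used as B cell Cre drivers (1 of 6 higher and 2 lower, adjusted p = 0.961). In all, 20 of 38 lists passed with the preset correlation, 18 higher and 2 lower, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 23 by fry. Dark zone genes had a median of 0.06 and a mean of -0.17, and camera put them lower. The 23 genes named from the lists passed on their own, with adjusted p at most 0.00485. The count of 885 genes fell to 465 with no filter on low counts, to 310 by DESeq2 and to 153 in a test against a minimum fold of 1.5, with 85.4%, 81.9% and 89.5% of those higher. It rose to 1388 with a replicate block, 68.7% of them higher. Over only the genes also tested in germinal center B cells, an alternative chosen after seeing the data, 618 passed, 73.8% of them higher.

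The design also allows the KO effects to be compared between the cell types, which share no library. Of 12514 genes tested in both, 325 rose in both, against 126 for independent lists (Fisher's exact test across genes, 2-sided p = 6.59e-84), and these were 67.6% of the 481 genes higher in KO activated B cells. Another 60 fell in both, against 46.6 for independent lists (Fisher's exact p = 0.0258). Opposite calls were 62 genes higher in germinal center and lower in activated B cells, against 47.6 (Fisher's exact p = 0.0173), and 74 genes lower in germinal center and higher in activated B cells, against 123 (Fisher's exact p = 4.67e-08). Genes are not independent replicates, so these p-values describe the lists. The genes higher in both included interferon-induced genes such as Mx1 and Oas2. They also included many immunoglobulin variable segments, erythroid genes such as Hba-a1 and Slc4a1, and myeloid genes such as Lyz2 and Itgam. How much of the overlap reflects other cells in the preparations was not tested. Across the 12514 genes the log2 fold changes of both cell types had Pearson's r of 0.206 and Spearman's rho of 0.0845. The 385 genes changed in the same direction became 131 by DESeq2 and 215 with no filter.

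**Figure D4:**
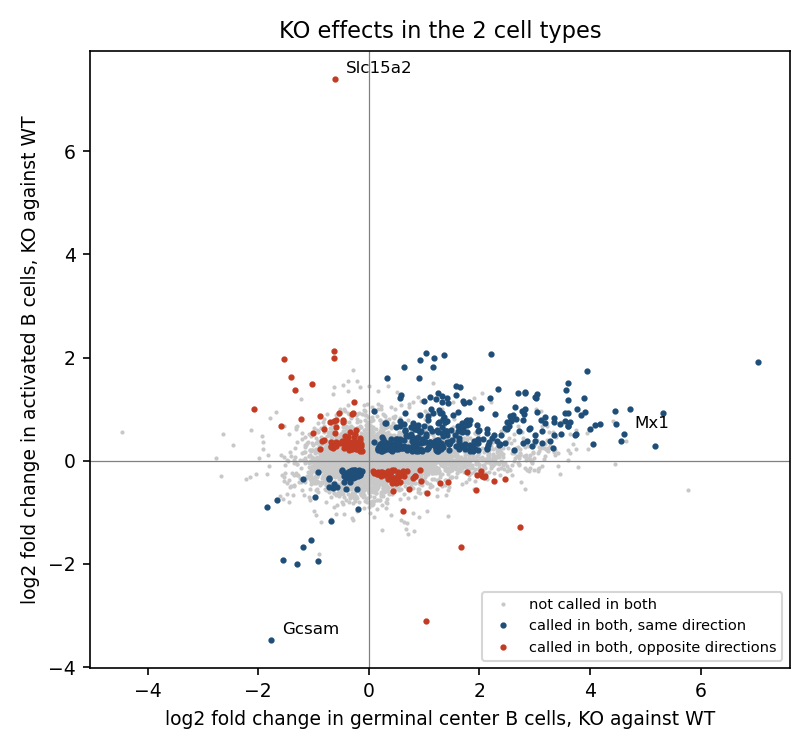
Log2 fold change of each gene, KO against WT, in germinal center B cells (horizontal) and activated B cells (vertical), with genes called in both coloured by whether the directions match. Mx1 lies at 4.62 on the horizontal axis, Gcsam falls in both at -1.76 and -3.47, and Slc15a2 lies at 7.40 on the vertical and -0.60 on the horizontal axis.

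In 1 fit over all 8 libraries, the KO effect differed between the cell types for 4685 of 14992 genes, 2621 with the higher value in germinal center B cells. The count was 2637 by DESeq2 and 918 against a minimum fold of 1.5. Slc15a2 had the lowest difference, -8.01 (SE 0.17, adjusted p = 4.92e-62), since it fell from 133 ± 2.45 to 87.1 ± 0.643 CPM in KO germinal center B cells and rose in KO activated B cells. Ighg2b differed by -2.75 (SE 0.07, adjusted p = 2.2e-55), lower in KO germinal center B cells at 436 ± 4.10 against 673 ± 5.47 CPM and higher in KO activated B cells. Ly6c2, a surface protein gene of monocytes and some lymphocytes, differed by 5.12 (SE 0.73, adjusted p = 1.09e-09), a value that rests on 1 count in WT germinal center B cells and ran from 4.39 to 7.35 with 1 library left out. It stood at 8.14 ± 1.92 against 0.0456 ± 0.0645 CPM in germinal center and 87.6 ± 15.5 against 23.1 ± 0.164 CPM in activated B cells. Rab44, a small GTPase gene, differed by -2.76 (SE 0.69, adjusted p = 0.000679), with a range of -3.05 to -2.43 when 1 library was left out.

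The other genes named by the rule were at or near 0 in germinal center B cells, so a fold there has no firm value. Gpnmb, a glycoprotein gene of macrophages (adjusted p = 0.000534), Iqgap2, a scaffold protein gene (0.0011), and Ptafr, the receptor gene for platelet-activating factor (0.00611), had 0 counts in WT and 0.541 ± 0.0764, 0.841 ± 0.157 and 0.538 ± 0.417 CPM in KO germinal center B cells. Camp (adjusted p = 0.0126) and Mmp9, a gelatinase gene of neutrophils (0.00651), had 0 counts in KO and 0.182 ± 0.258 and 0.235 ± 0.184 CPM in WT germinal center B cells. Without WT germinal center replicate 2, the difference did not pass for Ptafr (adjusted p = 0.0565), Camp (1, in a range of 0.00256 to 1 over all settings) or Mmp9 (0.188, in a range of 0.00432 to 0.188). Ptafr also did not pass without KO germinal center replicate 2 (adjusted p = 0.126, in a range of 0.0018 to 0.126).

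The WT libraries describe how the 2 cell preparations differ in the reference genotype. Germinal center B cells held far more transcripts of the cell cycle, the germinal center program and mitochondria, and activated B cells held more of glycolysis, interferon response, memory B cell and myeloid transcripts. Mki67, a proliferation marker gene, stood at 2720 ± 84.6 CPM in germinal center and 70.4 ± 1.29 CPM in activated B cells (log2 fold change 5.27, SE 0.06, adjusted p = 1.71e-151). Of 14426 genes tested, 11852 passed, 5816 higher and 6036 lower in germinal center B cells. Sorting against bead enrichment with stimulation is the same split as the cell type, so the values describe preparations, and 7776 genes passed against a minimum fold of 1.5. Jmjd1c was lower in WT germinal center than in WT activated B cells (-0.59, SE 0.05, adjusted p = 1.24e-24).

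All 43 G2 and M phase genes and 43 of 44 S phase genes were higher in WT germinal center B cells, with 0 lower and the same counts adjusted over the list alone. Their medians were 4.39 (camera adjusted p = 8.39e-28, and adjusted p = 0.236 with an estimated correlation) and 3.05 (camera adjusted p = 1.6e-24, and adjusted p = 0.236 with an estimated correlation). Top2a (4.82), the DNA methylation cofactor gene Uhrf1 (4.98) and the replicative helicase gene Mcm5 (4.29) were examples. Replication-dependent histone genes gave 25 of 28 higher, 0 lower and 3 not passing (25 and 0 adjusted over the list alone), with camera adjusted p = 0.00313, and adjusted p = 0.311 with an estimated correlation. Of 32 germinal center B cell genes, 28 were higher and 4 lower (28 and 4 adjusted over the list alone), with a median of 3.28 (camera adjusted p = 2.04e-11, and adjusted p = 0.236 with an estimated correlation). The transcription factor gene Mef2b (434 ± 3.99 against 4.88 ± 0.357 CPM) and the follicle-retention receptor gene S1pr2 (413 ± 3.47 against 6.50 ± 0.902 CPM) were examples. Dark zone genes gave 20 of 23 higher and 3 lower (20 and 3 adjusted over the list alone), with camera adjusted p = 8.68e-10, and adjusted p = 0.236 with an estimated correlation. Gcsam (6.06) and Cdc20 (5.33) were among them. Genes of somatic hypermutation and class switching gave 26 of 38 higher, 6 lower and 6 not passing (27 and 6 adjusted over the list alone), with camera adjusted p = 5.15e-06, and adjusted p = 0.236 with an estimated correlation. Genes used as B cell Cre drivers gave 4 of 6 higher, 0 lower and 2 not passing (4 and 0 adjusted over the list alone), with camera adjusted p = 0.0145, and adjusted p = 0.286 with an estimated correlation.

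Memory B cell genes gave 6 of 26 higher, 18 lower and 2 not passing (6 and 18 adjusted over the list alone), with a median of -2.38 (camera adjusted p = 3.96e-06, and adjusted p = 0.291 with an estimated correlation). Mature B cell identity genes gave 13 of 30 higher, 13 lower and 4 not passing (13 and 14 adjusted over the list alone) and did not pass (camera adjusted p = 0.377). Of the memory genes, S1pr1, the receptor gene for exit into the circulation, stood at 23.8 ± 0.870 CPM in WT germinal center and 429 ± 4.56 CPM in WT activated B cells, and Ccr7, the chemokine receptor gene of T zone homing, differed by -5.71. Ighd was lower (-4.65) and Ighg1 higher (6.15) in germinal center B cells, while immunoglobulin constant genes as a list gave 5 of 12 higher and 6 lower (5 and 6 adjusted over the list alone) and did not pass (camera adjusted p = 0.377). Interferon response genes gave 4 of 45 higher, 38 lower and 3 not passing (4 and 38 adjusted over the list alone), with a median of -1.89 (camera adjusted p = 3.74e-07, and adjusted p = 0.236 with an estimated correlation). Ifi203 (-3.61) and Ddx58 (-3.02) were examples. JAK-STAT3 and cytokine response genes gave 7 of 37 higher, 25 lower and 5 not passing (7 and 25 adjusted over the list alone), with camera adjusted p = 0.00612, and adjusted p = 0.236 with an estimated correlation. Marginal zone and B1 cell genes gave 7 of 24 higher, 14 lower and 3 not passing (7 and 14 adjusted over the list alone), with camera adjusted p = 0.0333, and adjusted p = 0.323 with an estimated correlation.

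Energy metabolism differed in both directions. Of 27 glycolysis genes, 25 were lower in WT germinal center B cells, 1 was higher and 1 did not pass (25 and 1 adjusted over the list alone), with a median of -1.82 (camera adjusted p = 7.43e-11, and adjusted p = 0.236 with an estimated correlation). Pdk1 (-3.35), a kinase gene that restrains pyruvate entry into mitochondria, and the aldolase gene Aldoc (-4.25) were examples. Nuclear oxidative phosphorylation genes gave 59 of 67 higher, 6 lower and 2 not passing (59 and 6 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 5.03e-12, and adjusted p = 0.311 with an estimated correlation), among them Cox6a1 (2.02). All 13 mitochondrially encoded genes were higher (13 and 0 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 2.58e-06, and adjusted p = 0.236 with an estimated correlation), among them mt-Cytb (1.97). Myc and ribosome biogenesis genes gave 38 of 45 higher, 1 lower and 6 not passing (38 and 1 adjusted over the list alone), with camera adjusted p = 1.61e-11, and adjusted p = 0.239 with an estimated correlation. The small ribosomal subunit assembly gene Bysl (2.46) was an example. Cytosolic ribosomal protein genes gave 46 of 78 higher, 22 lower and 10 not passing (46 and 22 adjusted over the list alone), with camera adjusted p = 0.0073, and adjusted p = 0.778 with an estimated correlation. Cholesterol synthesis genes gave 18 of 24 higher, 2 lower and 4 not passing (18 and 2 adjusted over the list alone), with camera adjusted p = 0.00381, and adjusted p = 0.236 with an estimated correlation.

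Markers of most other blood cells were lower in the sorted WT germinal center B cells than in the activated preparation. Dendritic cell markers, with 3 of 14 higher and 10 lower, did not pass as a list (camera adjusted p = 0.272). All 17 neutrophil markers tested were lower (17 adjusted over the list alone), with camera adjusted p = 8.8e-08, and adjusted p = 0.236 with an estimated correlation. Against a floor of 3 counts over the group, Ngp was at least 1360-fold lower (0 against 3895 counts), S100a9 at least 801-fold, Ltf at least 776-fold and Chil3 at least 353-fold. The macrophage genes Gpnmb and Clec4e, the latter a pattern receptor gene, were at least 872-fold and 436-fold lower. Of 24 monocyte and macrophage markers, 23 were lower and 1 higher (23 and 1 adjusted over the list alone), with camera adjusted p = 2.33e-08, and adjusted p = 0.26 with an estimated correlation, and Lyz2 stood at 0.303 ± 0.170 against 441 ± 30.9 CPM. Of 11 erythroid markers, 10 were lower and 1 did not pass (10 adjusted over the list alone), with camera adjusted p = 2.52e-05, and adjusted p = 0.236 with an estimated correlation, and Hbb-bs differed by -7.33. T cell markers gave 3 of 19 higher, 15 lower and 1 not passing (3 and 15 adjusted over the list alone), with camera adjusted p = 0.0498, and adjusted p = 0.291 with an estimated correlation. All 6 NK cell markers tested were lower (6 adjusted over the list alone), with camera adjusted p = 0.0324, and adjusted p = 0.291 with an estimated correlation.

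Within the limits for ranking, genes with the highest ratios in WT germinal center B cells included Slc15a2 (7.73, SE 0.15), the linker histone gene H1f10 (7.40, SE 0.15), the immediate early gene Fos (7.02, SE 0.11) and the endonuclease gene Ankle1 (6.93, SE 0.15). H1f10 is uncertain because 17.5% of its exon length overlaps exons on the opposite strand. Mir6236, an annotated microRNA locus, had 326 counts against 0, at least 104-fold higher. The embryonic hemoglobin gene Hbb-bh1 had 307 counts against 1, a ratio of 294 with a counting interval of 52.4 to 11700. In all, 22 of 39 lists passed with the preset correlation, 12 higher and 10 lower, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 34 by fry. The 22 genes named from the lists passed on their own, with adjusted p at most 1e-81.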

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

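All tests of explanations in this part were chosen after the results were seen, while the difference of the KO effects between cell types was planned. The results listed here were picked out because the KO effect differed between germinal center and activated B cells by edgeR's quasi-likelihood test over all 8 libraries, or because reads outside the gene counts differed between groups.

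The KO effect differed for 4685 genes, 31.2% of those tested. Of 105 named genes considered, 90 differed, with adjusted p at most 0.0323. Most named genes were picked for extreme folds or low p in these same libraries, so a high share was likely from the start. Values below are log2 differences of the KO effects, germinal center minus activated B cells. Jmjd1c differed by 0.74 and Slc15a2 by -8.01. Other genes named for this contrast were Ly6c2 (5.12, resting on 1 count in WT germinal center B cells and from 4.39 to 7.35 with 1 library left out), Rab44 (-2.76) and Ighg2b (-2.75). For genes with a group at 0 counts only the adjusted p is given: Gpnmb (0.000534), Iqgap2 (0.0011), Ptafr (0.00611), Camp (0.0126), Mmp9 (0.00651) and Ltf (0.0323).

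Picking genes by extreme folds in the same libraries makes such a difference likely. All 20 genes named for their fold change in germinal center B cells, ranked only among called genes with a mean count of at least 50, differed. These were Mx1 (4.09), Hba-a1 (3.75), Oas2 (3.47), Sdc3 (3.39), Plac8 (3.73), Ptpn14 (3.38), Tmem154 (2.95), Lgals3bp (3.36), Rtp4 (2.88) and Hbb-bs (2.94), and Celsr1 (-2.75), Nt5e (-1.87), Fgf11 (-1.84), Pcyt1b (-2.72), Igf2bp3 (-1.78), Osbpl3 (-2.05), Serpinf1 (-2.28), Fads2 (-2.13), Abi2 (-0.94) and Palm (-1.93). Among those of activated B cells were Ifi208 (4.14), Gad1 (1.72), Zfp827 (0.84), Pfn2 (-0.89), Rell1 (0.96) and Dnah8 (0.71).

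Among the germinal center, dark zone, hypermutation and cell cycle genes the differences were 1.71 (Gcsam), -0.65 (Cdc20), -0.50 (Polh), -0.68 (Mcm6), -0.64 (Top2a), -0.78 (Hmgb2) and -0.83 (Hmces). Light zone, memory, migration, marginal zone and immediate early genes gave Ccr6 (2.49), Cd69 (1.29), Klf2 (2.22), Ccr7 (2.92), S1pr1 (2.10), Notch2 (1.86), Cd36 (1.83), Jun (2.02) and Fosb (1.11). Immunoglobulin, interferon and antigen presentation genes gave Ighd (2.04), Ighm (1.64), Ighg1 (-1.21), Ighe (-2.62), Ifi203 (2.59), Ddx58 (2.46), Oasl2 (1.59), Ifit3 (1.78), H2-K1 (1.08), B2m (0.79) and Tap1 (0.44). Plasma cell, folding and signaling genes gave Irf4 (1.40), Zbtb20 (-0.73), Jchain (-0.63), Prdm1 (1.05), Pdia4 (1.60), Hspa5 (0.32), Il10ra (1.45), Nfkb1 (0.62), Il5ra (2.10), Cd9 (1.27) and Cd274 (1.99). Metabolic and chromatin genes gave mt-Co1 (0.67), mt-Cytb (0.72), Atp5b (-0.39), Cox6a1 (-0.56), Hmgcs1 (-0.98), Sqle (-0.86), Idi1 (-0.90), Cbx5 (-0.76) and Kdm7a (0.87). Markers of other cells and of sex gave Mpeg1 (1.79), Ctsb (0.47), Slc4a1 (4.38), Lyz2 (2.62), Tyrobp (1.72) and Eif2s3y (0.44).

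Reads aligned to several places lie outside the gene counts. They made up 9.22% ± 0.014 in KO against 6.93% ± 0.077 in WT germinal center B cells, and 4.66% ± 0.13 in KO against 4.45% ± 0.12 in WT activated B cells, each n = 2. The second pair differs by less than 2 SD, and neither was tested.

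Neutrophil, monocyte and erythroid markers were higher in KO activated B cells. A shift of all transcripts of similar abundance through scaling or depth is argued against. Medians of 10000 random lists matched on expression ran from -0.18 to 0.22, with a middle value of -0.01, against 1.78 for the neutrophil markers. The neutrophil list was taken up for its high median, so its lead was likely from the start. Only the small medians of the random lists bear on such a shift. A lower share of B cells with every other cell type raised alike is also argued against as the whole cause. Neutrophil markers rose by a median of 1.06 more than erythroid markers, with quartiles of 1.47 to 1.95 against 0.33 to 0.89. The medians of erythroid (0.71), NK cell (0.51), monocyte (0.50), T cell (0.46), dendritic cell (0.35) and stromal markers (0.25) lay closer together. The comparison therefore cannot exclude a lower share of B cells beside a separate rise of neutrophil markers. RNA from granulocytes left in the KO preparation remains a candidate explanation. In a second granulocyte list of 33 genes, sharing 0 with the first, 15 of 17 tested members whose effects had not been seen were called higher. The 8 further members had been seen, and all were higher. Ngp, S100a9 and Ltf reached 809, 473 and 407 CPM. However, 7 of the unseen members also passed the expression filter in germinal center B cells. Of these, Anxa1 (1.58), Pglyrp1 (1.68), Serpinb1a (2.79) and Il1r2 (1.78) were called higher in KO germinal center B cells too. Neutrophil markers there summed to only 3.04 CPM in KO and 1.04 CPM in WT. The rises of these genes therefore do not single out granulocyte RNA. Bead enrichment for B cells would remove most such cells but is no sort, and more granulocytes in KO spleens, less complete enrichment, and expression of these genes by B cells were not tested apart.

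Cell cycle genes were lower in KO germinal center B cells. Resting cells mixed into the KO sort could lower them, and the median of -0.41 over 87 S, G2 and M phase genes (quartiles -0.58 to -0.25, a fall of 24.8%) cannot be told apart from less cycling within the cells, because bulk counts mix both. For genes lower by more than 2-fold, a mixture with cells that hold no cell cycle transcripts is argued against as the whole cause. Of these genes, 71 lay beyond 2-fold by more than the 95% margin of their SE. A mixture with such cells that lowers cell cycle genes by 24.8% would lower no gene further. Mixed-in cells that hold some cell cycle transcripts could lower other genes further, so the values do not decide about them. The rises of Klf2, Ighd and the memory B cell, interferon response and other-cell marker lists were not tested apart from a mixture. FACS would remove resting cells only as far as its gates, which are not given in the sources used here, exclude them.

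Slc15a2 was near 0 in WT activated B cells alone, with raw counts of 7 and 5, against 1005 and 1053 in KO activated, 1282 and 1437 in WT and 719 and 728 in KO germinal center B cells. An effect of the KO common to both cell types is argued against, since the log2 fold change in germinal center B cells was -0.60. A block of another genome around Slc15a2 in the mice of 1 activated group could also give such a difference, and it stays open: 4.42% of 113 tested genes within 10 Mb were called (exact interval 1.45% to 10%) against 6.28% elsewhere (Fisher's exact p = 0.558), and positions of some of these genes had been seen before. A KO effect that needs the activated state also stays open, as untested.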

How the results depend on the processing

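The alternatives were fixed before the data were examined except 1, the activated comparison over only genes also tested in germinal center B cells, chosen after seeing the data (618 of 885 genes). Over 567 alternative values of named genes, 558 kept direction and call, 9 lost the call (Abi2, Pfn2, Ptafr, Camp and Mmp9) and 0 reversed. Of 114 alternative values of the main results, 100 stayed within 1.5 times or kept their call. A test against a minimum fold of 1.5, by construction stricter, gave 1247 genes in germinal center B cells, 153 in activated B cells, 918 for the difference of KO effects and 7776 between WT preparations. DESeq2 gave 310 genes in activated B cells, 2637 for the difference and 131 changed alike in both cell types, and no filter on low counts gave 465 in activated B cells and 215 changed alike, and the cause was not tested. With an estimated correlation 0 lists passed in germinal center B cells, 0 in activated B cells and 0 between WT preparations. That setting rests on 2 residual degrees of freedom, and its power was not measured. By fry, which tests another hypothesis, 34 lists were called between WT preparations.

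The labels share replicate numbers, but deviations of same-numbered libraries correlated at only -0.0787 to 0.0436 over 8073 genes. These values show no pairing by number, but with 2 libraries per group they cannot exclude a shared animal or day. With a replicate block 1388 genes passed in activated B cells, 6723 in germinal center B cells, 4889 for the difference and 11746 between WT preparations. Leaving out 1 library at a time gave 5669 to 5933 genes in germinal center B cells, 601 to 951 in activated B cells, 3851 to 4493 for the difference, 11392 to 11633 between WT preparations and 272 to 376 changed alike. Jmjd1c ranged from -0.28 to -0.14 in germinal center and from -1.03 to -0.86 in activated B cells. Lists numbered 26 to 30, 19 to 21 and 22. Of the list examples called, 124 to 126 of 126 kept the call in germinal center B cells, 51 to 84 of 84 in activated B cells and 141 of 141 between WT preparations, with 0 changes of sign. With 8777425 to 11414559 counts per library, genes of a few counts, such as those near 0 in germinal center B cells, carry no firm fold change.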

Other observations

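No test in this part was chosen after the results were seen, and the lists are those fixed before the data were examined. Genes of B cell migration moved in both directions in KO germinal center B cells, with 17 of 27 higher, 8 lower and 2 not passing (17 and 8 adjusted over the list alone). The median was 0.55 (camera adjusted p = 7.17e-14, and adjusted p = 0.0701 with an estimated correlation). Ccr7, the receptor gene for T zone chemokines, rose from 8.21 ± 0.457 to 65.4 ± 1.99 CPM, and S1pr1, the receptor gene for exit into the circulation, rose by 2.17. Marginal zone and B1 cell genes gave 19 of 24 higher, 1 lower and 4 not passing (19 and 1 adjusted over the list alone), with a median of 1.33 (camera adjusted p = 1.33e-17, and adjusted p = 0.0701 with an estimated correlation). Notch2 (1.92), a receptor gene needed for marginal zone B cells, and the scavenger receptor gene Cd36 (2.83) were examples. Immediate early and stress genes gave 16 of 28 higher, 6 lower and 6 not passing (16 and 6 adjusted over the list alone), with camera adjusted p = 1.48e-09, and adjusted p = 0.0701 with an estimated correlation. Jun (2.25) and Fosb (1.68), subunits of the AP-1 factor, rose. Costimulation and T cell help genes gave 12 of 20 higher, 4 lower and 4 not passing (13 and 4 adjusted over the list alone), with camera adjusted p = 0.0451, and adjusted p = 0.387 with an estimated correlation. Cd274, which encodes the checkpoint ligand PD-L1, rose by 1.77, and the ephrin gene Efnb1 changed by -1.44.

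Genes of somatic hypermutation and class switching gave 16 of 38 lower, 2 higher and 20 not passing in KO germinal center B cells (16 and 2 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.000279, and adjusted p = 0.121 with an estimated correlation). Besides Polh, Hmces, which shields abasic DNA sites, changed by -0.62. Cholesterol synthesis genes gave 15 of 24 lower, 1 higher and 8 not passing (15 and 1 adjusted over the list alone), with camera adjusted p = 0.00425, and adjusted p = 0.178 with an estimated correlation. Hmgcs1 (-0.69) and Sqle (-0.52), enzymes of the pathway, fell. The H3K9 methylation list, the class of histone mark that the knocked-out gene's family acts on, gave 6 of 21 higher, 10 lower and 5 not passing (6 and 12 adjusted over the list alone) and did not pass (camera adjusted p = 0.0717). Cbx5, which encodes the H3K9-binding protein HP1 alpha, changed by -0.79, and the demethylase gene Kdm7a by 0.72.

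In KO activated B cells, cholesterol synthesis genes gave 5 of 24 higher, 0 lower and 19 not passing (10 and 0 adjusted over the list alone), with camera adjusted p = 0.000696, and adjusted p = 0.247 with an estimated correlation, and the isomerase gene Idi1 rose by 0.55. Marginal zone and B1 cell genes gave 7 of 24 higher, 1 lower and 16 not passing (12 and 1 adjusted over the list alone), with camera adjusted p = 1.14e-05, and adjusted p = 0.247 with an estimated correlation, and the tetraspanin gene Cd9 rose by 0.69. Lists of migration (4 of 28 higher and 1 lower, camera adjusted p = 0.173), immediate early and stress (1 of 31 higher, adjusted p = 0.105), costimulation (1 of 20 higher and 1 lower, adjusted p = 0.48), hypermutation and class switching (2 of 38 lower, adjusted p = 0.0637) and H3K9 methylation genes (0 of 21 called, adjusted p = 0.105) did not pass. Ifi208, the lowest of the genes named by the fold rule in KO activated B cells, had raw counts of 327 and 414 in WT and 46 and 39 in KO activated B cells, against 29 and 32 in WT and 53 and 48 in KO germinal center B cells.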
